A study of Mus musculus with 12 samples.

How the data were processed

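Bulk RNA sequencing of mouse spinal cord tissue was analysed in 12 libraries from 4 groups of 3, as grouped by the submitters' labels: non-injured cord, spinal cord injury, and spinal cord injury followed by transplantation of syngeneic or of allogeneic mesenchymal stem cells. Per the labels' protocols, tissue was broken up mechanically in lysis buffer, RNA was purified on silica columns with a DNase step, and libraries were made with a strand-preserving kit after poly(A) selection. The time between injury and tissue collection, the donor strain of the cells, the sex and age of the mice and the length of cord taken are not given in the sources used here.

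The values are raw read counts per Ensembl gene for each library, as deposited by the authors in 1 table of 46078 genes, of which 45143 carry a symbol. The submitters' processing notes name FastQC 0.11.5, Trim Galore 0.4.1, STAR 2.5.1, StringTie 1.3.3, featureCounts 1.5.1, Picard and the genome build GRCm38, with no role or order. The annotation release, the strand setting of the counting and its treatment of reads that match several genes are not given in the sources used here. Values of genes whose exons overlap a gene on the other strand are therefore uncertain (among the genes named and looked up: Arntl, Bdnf, Bhlhe41, Cd3e, Cox5a, Csf1r, Ctsw, Cxcl10, Dbp, Fdft1, Fn1, Gbp2, Hmgcs1, Idi1, Igf2, Mmp11, Mmp12, Nefl, Nefm, Nr1d1, Pla2g3, Psmb8, Rarres2, S1pr3, Slamf7 and Tef). The same holds for genes with near-identical copies (H2-Q7, H2-D1, H2-K1, Ly6c2 and the Gimap family) and for Cd74, Igf2, Itgam and Top2a, which share exons with another gene of the same strand. Coordinates were taken from GENCODE M21 on GRCm38, in which 16461 of the 16527 genes tested were found by identifier. Xist, Fabp4, Gimap4, Gzmb, Lbhd2, Tspear and Gm32444 were not looked up for overlaps.

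Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 16527. Factors came from TMM, the trimmed mean of M values. The main test was edgeR 4.0.16 in R 4.3.3 with robust dispersions and robust quasi-likelihood (glmQLFit and glmQLFTest), on all 12 libraries with 1 mean per group and 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05, and a gene is called when its adjusted p lies below it. CPM values (counts scaled to a common library size) were computed from the deposited counts with TMM-scaled totals, log2 CPM with a prior count of 2, and fold changes are on the log2 scale with standard errors (SE) from the fit. Levels are group means ± SD (n = 3). The 4 main comparisons were injury against non-injured cord, each transplanted group against injury alone, and syngeneic against allogeneic cells; each transplanted group against non-injured cord was secondary.

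The comparisons, the tests, the rule for named genes and 37 gene lists were chosen before the data were examined. The lists cover microglia, phagocytic myeloid cells, blood-derived monocytes and macrophages, neutrophils, dendritic cells, T and natural killer (NK) cells, B cells, antigen presentation by class I and class II molecules of the major histocompatibility complex (MHC), interferon response, cytokines, complement, reactive and homeostatic astrocyte genes, scar proteoglycans, fibroblasts, mesenchymal stromal cells, bone and cartilage, myelin, oligodendrocyte precursors, Schwann cells, neurons, motor neurons, neurotransmission, endothelium, ependyma, meninges, cell cycle, trophic factors, axon growth, cholesterol synthesis, oxidative phosphorylation, immediate early and heat shock genes, red blood cells, skeletal muscle, adipocytes and sex-linked genes. Lists with at least 4 tested genes (35 of the 37) were tested with limma 3.58.1 camera with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Calls of list members are given over all genes tested and adjusted over the list alone. Genes named in the main comparisons are the 6 largest called rises and falls with mean log2 CPM of at least 1 and no overlap between the groups' libraries (chance gives 10% of genes such a separation with 3 against 3), the 2 called members with the smallest p of each called list, and Gfap, Aif1, Mbp, Snap25, Cd3e, Arg1, Tnf and Bdnf. Where at most 12 genes were called, all are named; the secondary comparisons name up to 3 rises and 3 falls, not every gene that the rule picked is printed, and any gene outside the rule is said to have been chosen after its values were seen.

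An injury index was computed per library as the mean log2 CPM of genes called higher minus that of genes called lower in the injured group left out of the comparison, against non-injured cord. It was compared between groups by a two-sided exact permutation test over 20 regroupings, whose smallest p is 0.1. Where a group held 0 counts of a gene, the fold change is given as a lower bound from a floor of 3 counts over the group; with 1 to 3 counts a ratio is given with its 95% counting interval. Floors and intervals cover counting error only.

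Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, RLE factors, library totals only, no filter and a filter of 1 CPM in 3 libraries, a fit of only the compared groups, an adjusted p below 0.01, a 2-fold minimum, and leaving out each library in turn. The injury index as a covariate and a fit without non-injured replicate 3 were added after seeing the data. The tests were tested on simulated data with 1 mean per gene pooled over all 12 libraries, the real library sizes and dispersions, and 200 changed genes. Genes were drawn independently, so spread shared by many genes within a group is absent. Recovery in the real data may therefore be lower. edgeR recovered 54% of the genes changed 2-fold and 89% of those changed 4-fold for syngeneic cells against injury alone, with 5 unchanged genes called, and 69% and 86% for allogeneic cells against injury alone, with 9 unchanged genes called. For syngeneic against allogeneic cells it recovered 64% and 86%, with 11 unchanged genes called, and for injury against non-injured cord 56% and 87%, with 9. DESeq2 called 34, 37, 44 and 51 unchanged genes in the same simulations. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9. No column of the table and no library was left out of the main test, and every entry of the table names a gene.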

Results

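RNA of mouse spinal cord tissue was sequenced in 12 libraries from 4 groups of 3. The groups were non-injured cord, spinal cord injury (SCI), and SCI followed by transplantation of mesenchymal stem cells (MSC), multipotent stromal cells, from a genetically matched (syngeneic) or unmatched (allogeneic) donor. The host strain in the labels is C57BL6/cJ. The labels do not say whether the 3 samples of a group are separate animals, so the p-values measure the spread between samples, which may in part be technical. By the numbers in their titles, syngeneic and allogeneic samples form ranges apart from each other and from the other groups. A sample set processed apart, if any, therefore cannot be separated from the transplant or its donor. Total counts were 16309022, 17750092 and 17341339 in the SCI libraries and 26151928, 15518403 and 21809868 in the non-injured libraries. They were 23027831, 24947862 and 15473549 with syngeneic cells and 15119497, 8705942 and 21265564 with allogeneic cells. Across genes, which are not independent replicates, libraries of a group correlated with r of 0.990 to 0.991 in SCI, 0.977 to 0.983 in the syngeneic, 0.972 to 0.981 in the allogeneic and 0.971 to 0.991 in the non-injured group. Syngeneic replicate 3 correlated more with the SCI libraries (0.989 to 0.991) than with its own group (0.977 and 0.982). So did allogeneic replicate 1, at 0.984 to 0.987 with SCI and 0.972 and 0.973 with its own group. The first principal component held 59.9% of the variance and placed the non-injured libraries at 66.6 to 80.5 and the SCI libraries at -39.0 to -29.6. Syngeneic replicates 1 and 2 lay between them at 12.9 and 27.2, whereas syngeneic replicate 3 (-27.4) and the allogeneic libraries (-57.0 to -24.9) lay on the SCI side. Non-injured replicate 3 stood apart on the second component (-56.2, against 14.6 and 15.5 in the other non-injured libraries), with 10.9% of its counts from mitochondrial genes against 4.998% to 8.80% in the other 11 libraries. Xist, the only sex-linked gene tested, was present in all 12 libraries (480 to 867 CPM).

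The comparison of SCI with non-injured cord asked what injury changed in the tissue without cells. All 12 microglial genes tested rose, among them Csf1r, the receptor that keeps microglia alive (357 ± 39.4 CPM against 73.7 ± 9.83, n = 3), and Aif1, which encodes the microglial protein IBA1 (log2 fold change 2.61, SE 0.26). Phagocytic and lipid-handling myeloid genes rose in 19 of 20 cases, led by Itgax, an integrin of activated myeloid cells (ENSMUSG00000030789, chromosome 7, 128129547 to 128150657; 7.02, SE 0.53), and the glucan receptor Clec7a (6.45, SE 0.50). Of the genes of blood-derived monocytes and macrophages 13 of 14 rose (14 adjusted over the list alone), with the antibody receptor Fcgr1 at 3.30 (SE 0.28) and Itgam at 2.74 (SE 0.27). Of the neutrophil genes 6 of 9 rose (8 adjusted over the list alone), including the growth factor receptor Csf3r (2.84, SE 0.30) and lactoferrin, Ltf (2.11, SE 0.39). T and NK cell genes rose in 10 of 16 cases (12 adjusted over the list alone) from very low levels. Cd3e, a chain of the T cell receptor complex, had 30 counts in SCI and 2 in non-injured cord, a ratio of 17.6 (95% counting interval 4.48 to 152). Cd8a, a chain of the cytotoxic T cell co-receptor, had 34 counts in SCI and 0 in non-injured cord, at least 13.3-fold higher.

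Of the largest rises in SCI, Mcoln3, an endolysosomal cation channel, was at least 148-fold higher and Slamf7, a leukocyte surface receptor, at least 118-fold higher, since non-injured libraries held 0 counts of either. Atp6v0d2, a proton pump subunit of macrophages and osteoclasts, had 1230 counts against 1, a ratio of 1447 (259 to 57206), and Cd200r4, a myeloid receptor, a ratio of 381 (67.9 to 15103). Ccn5, a matricellular protein, rose by a log2 fold change of 8.47 (SE 0.77) and Mmp12, macrophage elastase, by 7.99 (SE 0.75). All 10 genes of MHC class II presentation rose, including Cd74, the invariant chain (4.59, SE 0.51), and H2-Aa (4.88, SE 0.57). Of the MHC class I genes 12 of 13 rose, with the immunoproteasome subunit Psmb8 at 2.62 (SE 0.25) and H2-D1, which has near-identical relatives, at 2.06 (SE 0.22). Interferon response genes rose in 21 of 22 cases (22 adjusted over the list alone), with the chemokine Cxcl10 at 5.65 (SE 0.55) and the guanylate-binding protein Gbp2 at 2.67 (SE 0.33). Cytokine and chemokine genes rose in 14 of 16 cases (14 higher and 1 lower adjusted over the list alone), among them Ccl3 (5.41, SE 0.34) and the interleukin 1 receptor antagonist Il1rn (207 counts against 2, ratio 122, 33.3 to 1012). All 11 complement genes rose, including C4b (674 ± 100.1 CPM against 50.3 ± 15.02) and the receptor C3ar1 (4.74, SE 0.50). Tnf rose by 3.94 (SE 0.56) and Arg1, an arginase of alternatively activated macrophages, by 1.80 (SE 0.55).

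In SCI, Gfap, the astrocyte filament protein, rose to 6525 ± 667 CPM from 1585 ± 619, and reactive astrocyte genes rose in 13 of 14 cases (14 adjusted over the list alone), with the lipid receptor S1pr3 at 3.22 (SE 0.26) and the protease inhibitor Timp1 at 5.96 (SE 0.54). Fibroblast and fibrillar matrix genes rose in 13 of 16 cases (14 over the list alone), with Thbs2 at 2.55 (SE 0.25) and fibronectin, Fn1, at 2.43 (SE 0.34). Cell cycle genes rose in 11 of 15 cases (13 over the list alone), with Top2a at 3.32 (SE 0.35) and Rrm2 at 1.43 (SE 0.16). Genes of axon growth and the injury response rose in 10 of 16 cases (13 over the list alone), led by Sprr1a, a regeneration-associated gene (7.18, SE 0.57; chromosome 3, 92483952 to 92485895), and Socs3 (3.66, SE 0.41). Meningeal genes rose in 5 of 10 cases (5 over the list alone), with Aldh1a2 at 2.51 (SE 0.57) and Igf2 at 3.73 (SE 0.88), and ependymal genes in 3 of 10 (5 over the list alone), with Rarres2 at 1.79 (SE 0.26) and Foxj1 at 0.41 (SE 0.089).

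All 16 genes of cholesterol synthesis fell in SCI. Hmgcs1, the first committed enzyme of the pathway (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), fell to 260.5 ± 55.9 CPM from 1167 ± 572 (-2.16, SE 0.38), with Msmo1 at -1.95 (SE 0.33), Mvd at -1.89 (SE 0.29) and Fdft1 at -1.42 (SE 0.20). Myelin genes fell in 7 of 12 cases (10 adjusted over the list alone), with Mal at -1.11 (SE 0.25) and Ugt8a, which makes the main myelin lipid, at -1.40 (SE 0.34). Mbp, myelin basic protein, had a log2 fold change of -0.72 (SE 0.36) and was not called. Non-injured replicate 3 held the highest mean of both lists, at 0.47 on the log2 scale for cholesterol synthesis (other non-injured libraries -0.18 and -0.28) and 0.63 for myelin (-0.20 and -0.43). Neuronal genes fell in 9 of 13 cases (10 over the list alone), with the neurofilament genes Nefl (1694 ± 246 CPM against 3179 ± 524) and Nefm (-0.98, SE 0.20), and Snap25, a synaptic vesicle fusion protein, fell by 0.79 on the log2 scale (SE 0.17). Motor neuron genes fell in 5 of 10 cases (8 over the list alone), including Chodl (-1.34, SE 0.33) and the choline transporter Slc5a7 (-0.77, SE 0.20). Genes of oxidative phosphorylation fell in 12 of 14 cases (14 over the list alone), with Cycs at -0.67 (SE 0.12) and Cox5a at -0.90 (SE 0.20). Other large falls were Aqp6 (-2.11, SE 0.42), the secreted phospholipase Pla2g3 (-1.90, SE 0.32) and Dmrta1 (-1.87, SE 0.62; -2.17 to -1.04 with 1 library left out, at an adjusted p of up to 0.197), while the neurotrophin Bdnf stood at 0.42 (SE 0.25) without a call. Of the called genes named in this comparison, Arg1, Chodl, Dmrta1, Igf2, Slc5a7 and Ugt8a lost their call in at least 1 alternative.

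In edgeR 2736 genes were called higher and 1530 lower in SCI than in non-injured cord. With library totals as the only scaling the counts were 3054 and 1089, which is 73.7% higher calls against 64.1%. The limma camera test called 21 of 35 lists, but none of the 21 held with an estimated correlation (adjusted p = 0.164 to 0.441 with an estimated correlation, 6 of 35 lists at an unadjusted p below 0.05), whereas fry called 26. The medians of the lists that limma camera placed higher were 3.63 for complement, 3.56 for phagocytic myeloid, 3.39 for cytokine, 3.31 for MHC class II, 3.03 for reactive astrocyte, 2.97 for monocyte, 2.44 for meningeal, 2.37 for fibroblast, 2.14 for microglial, 2.07 for MHC class I, 1.86 for cell cycle, 1.82 for interferon, 1.61 for neutrophil, 0.82 for axon growth and 0.79 for ependymal genes. The median of the T and NK list was 2.80, or 2.35 with the 4 members without counts in non-injured cord at their bound. The lists it placed lower had medians of -1.57 for cholesterol synthesis, -0.81 for motor neurons, -0.76 for myelin, -0.61 for oxidative phosphorylation and -0.59 for neurons. The 14 lists without a camera call (adjusted p = 0.0724 to 0.937) held 1 higher and 1 lower of 7 dendritic cell genes, 1 higher of 6 B cell genes, 4 and 2 of 12 homeostatic astrocyte genes, 7 and 2 of 13 scar proteoglycan genes, and 4 and 1 of 12 mesenchymal stromal genes. They also held 3 higher of 7 bone and cartilage genes, 4 of 11 oligodendrocyte precursor genes, 2 of 11 Schwann cell genes, 2 of 14 endothelial genes, 5 higher and 1 lower of 13 trophic factor genes and 5 and 1 of 12 immediate early and heat shock genes. In edgeR 0 of 16 neurotransmission and 0 of 7 red blood cell genes and 1 of 6 skeletal muscle genes, which was lower, were called. The median of the neurotransmission list (-0.06) had the other sign than its mean and test. limma-voom called 8229 genes. edgeR called 2336 genes without SCI replicate 2, 2747 without SCI replicate 3 and 2757 without non-injured replicate 1.

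**Figure D1:**
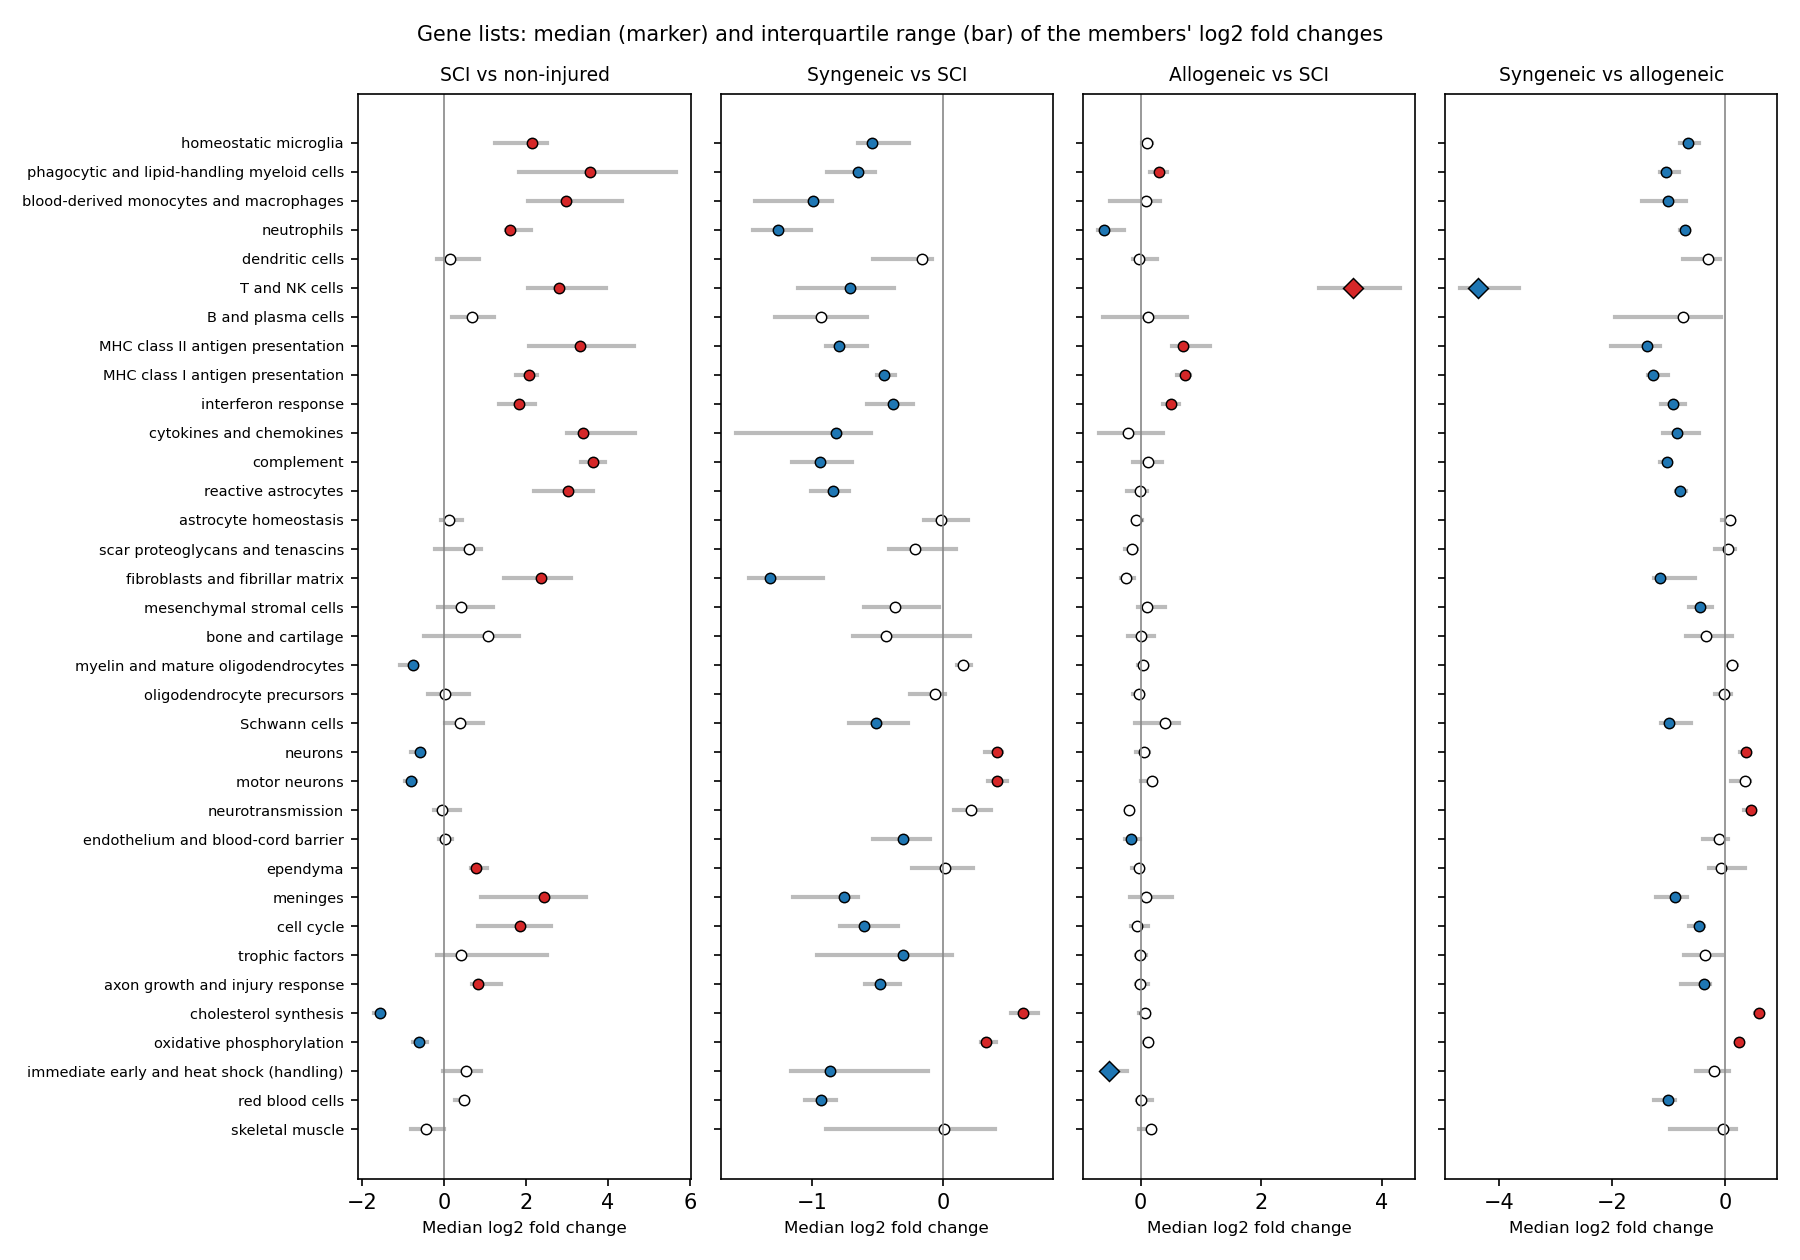
Median log2 fold change (marker) and interquartile range (bar) of 35 gene lists in the 4 main comparisons, with a separate horizontal scale in each panel; filled red and blue markers are lists called higher or lower by limma camera, white markers were not called, and diamonds were also called with an estimated correlation. The T and NK list stands at 3.52 in allogeneic against SCI and -4.38 in syngeneic against allogeneic.

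The comparison of SCI with syngeneic cells against SCI alone asked what a transplant from a matched donor changed. The group label of SCI alone names no control procedure, so differences from it may include effects of the transplantation procedure itself. Only 6 genes were called in edgeR, 1 higher and 5 lower. Dbp, a transcription factor that follows the circadian clock, was higher (72.0 ± 6.16 CPM against 21.1 ± 0.423, n = 3; log2 fold change 1.77, SE 0.21, adjusted p = 0.0152; ENSMUSG00000059824, chromosome 7, 45705088 to 45710203). Arntl, which encodes the clock activator BMAL1 (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), fell to 9.24 ± 0.796 from 21.6 ± 1.19 CPM (-1.22, SE 0.12, adjusted p = 0.00576). Fos, an immediate early gene (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), fell to 33.3 ± 8.98 from 122 ± 22.7 CPM (-1.88, SE 0.23). The basement membrane gene Frem2 (ENSMUSG00000037016, chromosome 3, 53513938 to 53657355) fell by 1.09 on the log2 scale (SE 0.13), the matrix protease gene Mmp11 (ENSMUSG00000000901, chromosome 10, 75923222 to 75936496) by 1.53 (SE 0.20), and Clec4e, a macrophage receptor for damaged cells, was at -3.41 (SE 0.46; 7 counts against 66; ENSMUSG00000030142, chromosome 6, 123281789 to 123289870). For each of the 6 genes the 3 libraries of a group did not overlap with those of the other.

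Between syngeneic cells and SCI alone limma camera placed 20 lists lower and 4 higher, but none held with an estimated correlation (adjusted p = 0.0917 for immediate early genes and up to 0.516 for the others with an estimated correlation, 7 lists at an unadjusted p below 0.05), and fry called 10. Fos was the only list member called over all genes. Among the lists placed lower the fibroblast median was -1.32 (5 of 16 genes lower adjusted over the list alone), the neutrophil median -1.26 (7 of 9), the monocyte median -0.99 (4 of 14) and the cytokine median -0.82 (5 of 16). Complement (-0.94), MHC class II (-0.79), T and NK cells (-0.71), phagocytic myeloid genes (-0.65), microglia (-0.54), MHC class I (-0.45), interferon response (-0.38) and Schwann cells (-0.51) had 0 members called adjusted over the list alone (edgeR, as for the whole set of genes), as did meninges (-0.76). Reactive astrocyte genes (-0.84), endothelium (-0.31) and trophic factors (-0.31) had 1 member each over the list alone, cell cycle (-0.60) 3, axon growth (-0.48) 4, red blood cells (-0.93) 5 of 7 and the immediate early and heat shock list (-0.86) 7 of 12. The lists placed higher were neurons (0.42, 7 of 13 over the list alone), cholesterol synthesis (0.62, 5 of 16), motor neurons (0.42, 0 of 10) and oxidative phosphorylation (0.33, 0 of 14). The 11 uncalled lists (adjusted p = 0.0654 to 0.952) included B cells (-0.93), mesenchymal stromal cells (-0.36), myelin (0.16) and oligodendrocyte precursors (-0.06). Dendritic cells (-0.16), scar proteoglycans (-0.22), bone and cartilage (-0.43) and neurotransmission (0.22) were also among them, and so were homeostatic astrocyte genes (-0.01), ependyma (0.02) and skeletal muscle (0.01), in which the median, mean and test differed in sign.

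The list means of the syngeneic libraries were not alike. The fibroblast list lay at 0.26 and 0.45 on the log2 scale above the non-injured mean in syngeneic replicates 1 and 2 and at 2.02 in replicate 3, against 2.20 to 2.65 in SCI. The immediate early and heat shock list, which can rise during dissection, lay at -0.35 to -0.09 in the 3 syngeneic, -0.15 to 0.05 in the allogeneic and 0.38 to 0.58 in the SCI libraries. Values of genes fixed in advance and not called were Gfap -0.54 (SE 0.27), Aif1 -0.55 (SE 0.24), Mbp 0.04 (SE 0.36), Snap25 0.54 (SE 0.17), Cd3e -1.06 (SE 0.45), Arg1 -1.69 (SE 0.54), Tnf -0.61 (SE 0.39) and Bdnf -0.22 (SE 0.25). The Mbp value turned to -0.15 in limma-voom. At an unadjusted p below 0.05 edgeR gave 2232 genes, DESeq2 called 121 and limma-voom 38. edgeR called 866 genes without syngeneic replicate 3. It called 0 when any other library was left out (SCI replicate 1, 2 or 3, or syngeneic replicate 1 or 2), with the smallest adjusted p at 0.0501 to 0.0829 and 990.0 to 1727 genes at an unadjusted p below 0.05.

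An injury index, the mean log2 level of genes raised by injury minus that of genes lowered by it, gave each library a position relative to non-injured cord and SCI. With genes taken from SCI against non-injured cord, the syngeneic libraries stood at 55.5%, 34.3% and 87.1% of the SCI mean and the allogeneic libraries at 88.3%, 110.0% and 101%. Genes chosen in a group favour a high value for it, and the syngeneic libraries stood at 57.2%, 39.6% and 92.3% with genes from allogeneic against non-injured cord and at 82.2%, 60.6% and 107.8% with genes from their own group. The allogeneic libraries stood at 101.6%, 117.58% and 117.61% with genes from syngeneic against non-injured cord. Syngeneic libraries lay 0.881 below allogeneic ones (1.27 ± 0.573 against 2.15 ± 0.235, n = 3; exact permutation p = 0.1, two-sided, the smallest of 20 regroupings). With genes from allogeneic against non-injured cord, the syngeneic libraries differed from SCI by -0.770 (1.31 ± 0.559 against 2.08 ± 0.119; exact permutation p = 0.1). With genes from syngeneic against non-injured cord, the allogeneic libraries differed from SCI by 0.380 (3.48 ± 0.285 against 3.10 ± 0.168; exact permutation p = 0.2). The 3 comparisons form 1 family, and no p below 0.05 is possible in it before or after adjustment.

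**Figure D2:**
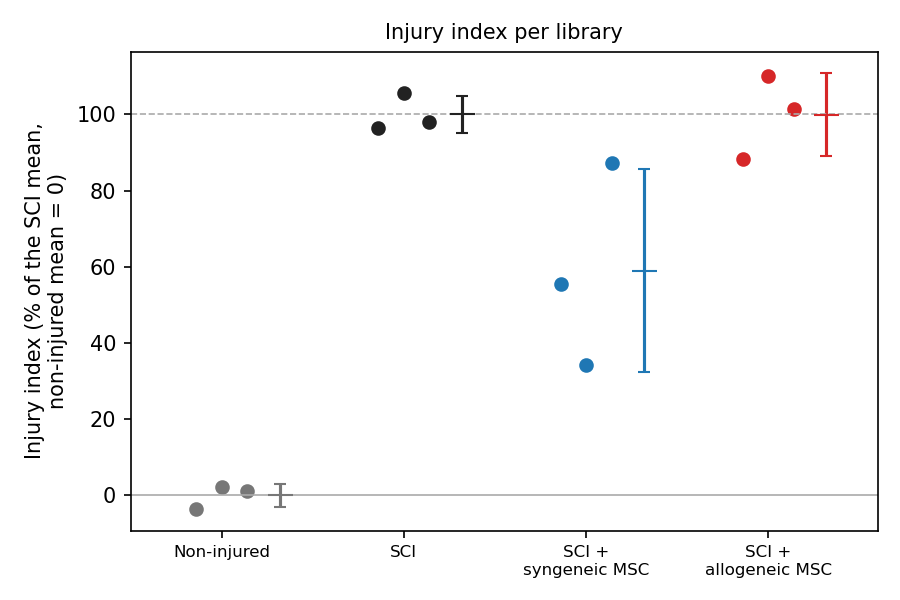
Injury index of each library as a percentage of the SCI mean, with the non-injured mean at 0, from genes called between SCI and non-injured cord, a choice that favours a high value in SCI; points are libraries and bars are the mean ± SD (n = 3). The syngeneic libraries spread from 34.3% to 87.1%, and the allogeneic libraries from 88.3% to 110.0%.

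The comparison of SCI with allogeneic cells against SCI alone asked what a transplant from an unmatched donor changed. The same limit on the label of SCI alone applies. T and NK cell genes rose in 10 of 16 cases (15 adjusted over the list alone). Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173) rose to 17.5 ± 7.10 CPM from 0.652 ± 0.0759 (n = 3; adjusted p = 0.00400) and Cd8b1 (ENSMUSG00000053044, chromosome 6, 71322788 to 71337494), the other chain of the CD8 co-receptor, to 10.1 ± 4.25 from 0.402 ± 0.163. Cd3g, of the T cell receptor complex, rose by 4.33 (SE 0.50) on the log2 scale and Cd3e by 3.35 (SE 0.36). Cxcr6, a chemokine receptor of tissue-resident T cells, rose by 3.82 (SE 0.52), Ms4a4b, a T cell membrane protein, by 3.58 (SE 0.41), and Ctsw, a protease of cytotoxic lymphocytes, by 3.17 (SE 0.40). Among genes chosen after their values were seen, the receptors Cxcr3 (3.14), Itgae (2.60) and Tigit (3.94) and the lymphocyte GTPase gene Gimap4 (2.29) were also higher. Itgae belongs to the dendritic cell list, which was not called as a list, and not to the T and NK list. The helper T cell gene Cd4 (0.92), the receptor constant regions Trac (1.32) and Trbc2 (2.81) and granzyme B, Gzmb (3.71, adjusted p = 0.0582), were not called.

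MHC class I genes had a median of 0.74 between allogeneic cells and SCI alone, with 1 of 13 called, H2-Q7 (2.09, SE 0.30), a gene with near-identical relatives, and 11 over the list alone. MHC class II genes (0.70, 4 of 10 over the list alone) and interferon response genes (0.51) and phagocytic myeloid genes (0.30), both with 0 members called by edgeR in either adjustment, were lists placed higher by limma camera. The T and NK list (median 3.52, adjusted p = 1.91e-65) was called also with an estimated correlation (adjusted p = 0.00212), whereas MHC class I (0.147), MHC class II (0.348), interferon (0.894) and phagocytic genes (0.907) were not; these 4 values are adjusted p with an estimated correlation. Lower lists were immediate early and heat shock genes (-0.53, 1 of 12 called and 4 over the list alone; adjusted p = 0.0198 with an estimated correlation), neutrophils (-0.61; 0.894) and endothelium (-0.15; 0.907), the last with 0 of 14 members called. Fos fell to 45.8 ± 11.9 CPM (-1.42, SE 0.23), and the clock activators Npas2 (-1.21, SE 0.20; ENSMUSG00000026077, chromosome 1, 39193731 to 39363236) and Arntl (-1.06, SE 0.12) fell, while Dbp rose by 1.68 (SE 0.21). The 27 uncalled lists had adjusted p from 0.0624 to 0.979. They included microglia (0.11), monocytes (0.08), dendritic cells (-0.03), B cells (0.12), cytokines (-0.21), complement (0.13), reactive (-0.01) and homeostatic (-0.08) astrocyte genes, fibroblasts (-0.24), mesenchymal stromal cells (0.10), myelin (0.04), Schwann cells (0.40), neurons (0.05), cell cycle (-0.07) and cholesterol synthesis (0.07). In the dendritic, bone and cartilage (0.0037), meningeal (0.09) and red blood cell (-0.00059) lists the median, mean and test differed in sign. The values of Gfap (-0.0027, SE 0.27), Aif1 (0.32), Mbp (0.04), Snap25 (0.02), Arg1 (-0.62), Tnf (0.39) and Bdnf (-0.15) were not called.

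edgeR called 28 genes higher and 3 lower in the allogeneic group than in SCI alone, with 486 genes at an unadjusted p below 0.05. Of the 31 genes 10 belong to the T and NK list and 17 to none of the lists, and 27 of the 28 higher genes, all but Dbp, were also higher in the allogeneic than in the syngeneic group. Both comparisons share the allogeneic libraries, so that overlap is not independent. DESeq2 called 69 genes, limma-voom 87 and a fit of both groups alone 17. Without SCI replicate 1, 2 or 3 edgeR called 0 genes, with the smallest adjusted p at 0.0513 to 0.0579 and 304 to 427 genes at an unadjusted p below 0.05. The sign of Gfap turned under RLE factors (0.00997), library totals (0.0024), a fit of both groups alone (0.0027), DESeq2 (0.00996) and limma-voom (0.17), and that of Snap25 in limma-voom (-0.082).

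**Figure D3:**
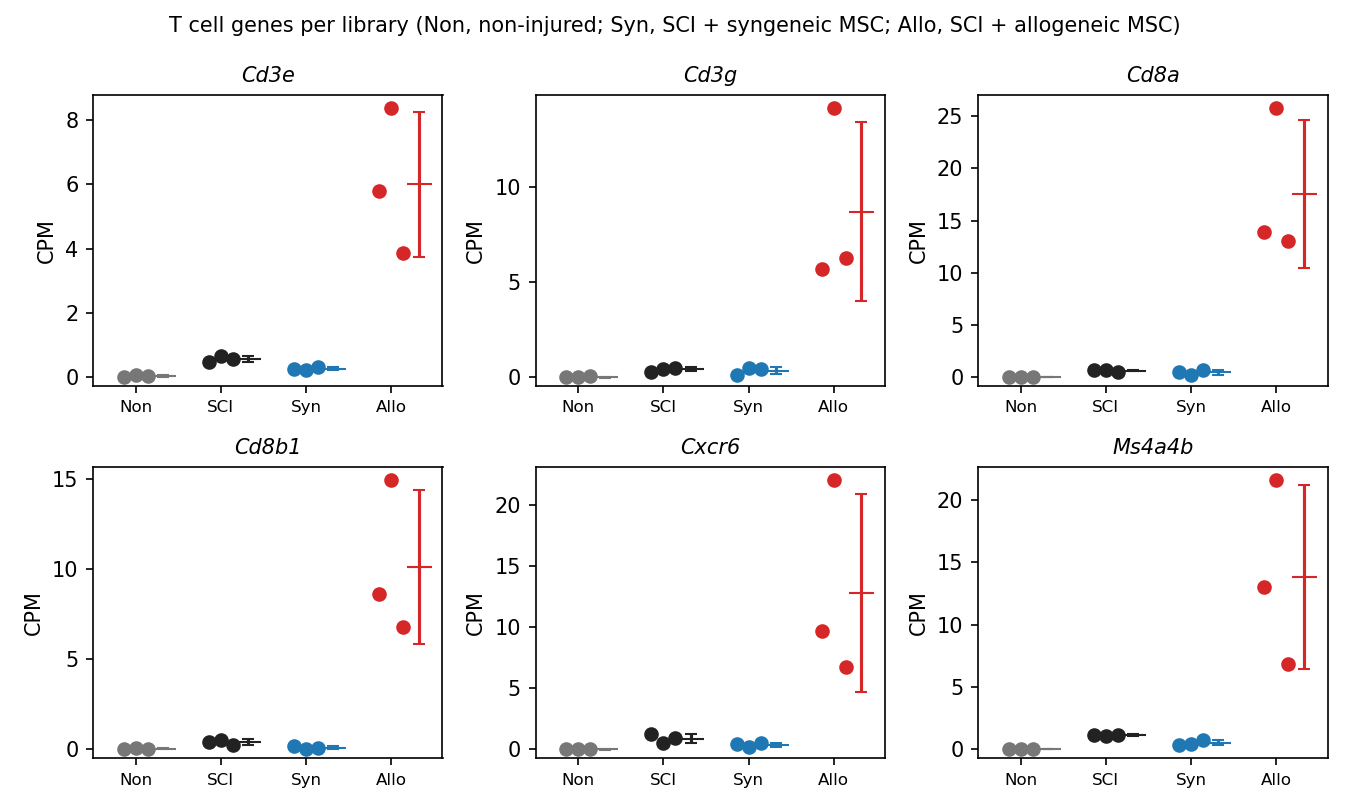
CPM of 6 T cell genes per library in the non-injured (Non), SCI, syngeneic (Syn) and allogeneic (Allo) groups; points are libraries and bars are the mean ± SD (n = 3), with a separate vertical scale for each gene. In Cd8a the allogeneic mean was 17.5 CPM, against 0.652 in SCI, 0.507 in the syngeneic group and 0 in non-injured cord.

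The direct comparison of syngeneic with allogeneic cells asked how the match between donor and host changed the tissue. T and NK cell genes were lower with syngeneic cells in 13 of 16 cases (16 adjusted over the list alone; median -4.38, limma camera adjusted p = 4.92e-36, and adjusted p = 0.0168 with an estimated correlation). Cd8b1 was at 0.0933 ± 0.0716 CPM with syngeneic and 10.1 ± 4.25 with allogeneic cells (-6.62, SE 0.54), and Cd8a at 0.507 ± 0.237 against 17.5 ± 7.10 (-5.14, SE 0.41). Cxcr6 (-5.12, SE 0.57), Ms4a4b (-4.70, SE 0.44), Cd3g (-4.58, SE 0.51), Cd3e (-4.41, SE 0.39) and Ctsw (-3.63, SE 0.41) were lower in the same direction. Tigit, an inhibitory T cell receptor chosen after its values were seen, had 0 counts with syngeneic cells and 58 with allogeneic cells, at least 26.5-fold higher in the latter. Ccl5, a chemokine of T cells, was the called member of the cytokine list (1.59 ± 0.376 against 16.7 ± 5.86 CPM), and Ly6c2, a monocyte gene that CD8 T cells also express and that has a near-identical copy, that of the monocyte list (-3.70, SE 0.49).

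Between syngeneic and allogeneic cells limma camera placed 18 lists lower and 4 higher, of which only the T and NK list held with an estimated correlation (adjusted p = 0.242 to 0.511 with an estimated correlation for the others; 4 lists at an unadjusted p below 0.05), and fry called 10. MHC class I genes had 6 of 13 members called lower (12 over the list alone; median -1.28, adjusted p = 0.242 with an estimated correlation), with H2-D1 at 220 ± 64.1 against 537 ± 79.9 CPM and H2-Q7 at -2.27 (SE 0.31). MHC class II genes had 1 of 10 called, Cd74 (35.9 ± 22.7 against 163 ± 56.7 CPM; adjusted p = 0.0456), and 9 over the list alone (median -1.39, adjusted p = 0.242 with an estimated correlation). Interferon response genes (median -0.93), phagocytic genes (-1.05), microglia (-0.67), complement (-1.04) and reactive astrocyte genes (-0.81) had 19 of 22, 18 of 20, 8 of 12, 5 of 11 and 2 of 14 members lower over the list alone, and 0 by edgeR over all genes. Monocytes (-1.02, 1 of 14 called and 6 over the list alone), cytokines (-0.87, 1 and 5 of 16), cell cycle (-0.47, 1 over the list alone), axon growth (-0.39, 2) and red blood cells (-1.01, 6 of 7) were also placed lower. Neutrophils (-0.73), fibroblasts (-1.15), mesenchymal stromal cells (-0.45), Schwann cells (-1.01) and meninges (-0.89) were placed lower by limma camera alone, with 0 members called by edgeR in either adjustment. Lists placed higher were cholesterol synthesis (0.58), neurotransmission (0.45), neurons (0.36) and oxidative phosphorylation (0.23), also with 0 members called. The 13 uncalled lists had adjusted p from 0.0696 to 0.804, among them motor neurons (0.35), B cells (-0.76), dendritic cells (-0.30, 1 of 7 lower), trophic factors (-0.37) and myelin (0.12). In scar proteoglycans (0.05) and ependyma (-0.08) the median, mean and test differed in sign.

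Of 101 genes called by edgeR between the transplanted groups, 98 were lower and 3 higher with syngeneic cells, with 2381 at an unadjusted p below 0.05. The 3 higher genes, named after their values were seen, were Lbhd2 (1.68), Tspear (2.01) and Gm32444 (1.34). Genes called higher fell to 1 with library totals as the only scaling, and edgeR called 0 higher without a filter, at an adjusted p below 0.01, in a fit of both groups alone (21 called in all, with all 21 lower), and without syngeneic replicate 1 or 2 or allogeneic replicate 2 or 3. The T and NK list held 13 of the 101, and 78 belonged to none of the lists. Gfap (-0.54), Aif1 (-0.87), Mbp (-0.0091), Snap25 (0.52), Arg1 (-1.07), Tnf (-1.002) and Bdnf (-0.07) were not called, and Bdnf turned to 0.069 in limma-voom and Mbp to 0.016 without a filter. DESeq2 called 347 genes, limma-voom 371 and a fit of both groups alone 21. edgeR called 1178 without syngeneic replicate 3, 24 without syngeneic replicate 1, 25 without syngeneic replicate 2 and 46 without allogeneic replicate 2.

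The comparisons of the transplanted groups with SCI share the SCI libraries. Dbp was called higher and Arntl and Fos lower in both, where independent lists would share 0.00169 higher and 0.000908 lower genes. Those numbers ignore the shared libraries. A test added after the data were seen took lists of the same sizes by smallest p from 40 simulations of unchanged groups. They shared a mean of 0.475 higher and 0.275 lower genes, and at most 1 of each. The syngeneic list of higher genes holds 1 gene, so it could share no more than that. The real overlap of 1 higher gene lay within the simulations, and that of 2 lower genes above them. Over all 16527 genes the fold changes of both comparisons correlated with r = 0.0869 across genes, against 0.497 (0.470 to 0.519) in the 40 simulations of unchanged groups. These redrew every library, with the injured ones from a mean pooled over their 3 groups and dispersions shared by all groups. The covariance was 0.0112, against a simulated 0.0451 (0.0410 to 0.0479) and 0.0198 from the variance of log2 CPM among the SCI libraries over 3. The simulated value lay above that of the real SCI libraries, so the simulations do not show what r the real libraries alone would give. The SD of the covariance over the fits without 1 library was 0.0141, and the covariance turned to -0.00918 without allogeneic replicate 1. It was 0.0282 without SCI replicate 1, 0.0302 without SCI replicate 2 and 0.0337 without allogeneic replicate 2. The 3 SCI libraries cannot be split so that each part keeps 2, and part of the shared calls may come from the shared libraries.

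The clock genes called with both kinds of cells led to a list of 15 genes of the circadian clock, chosen after values were seen. In syngeneic cells against SCI 2 were called (12 adjusted over the list alone), and in allogeneic cells against SCI 3 (10 over the list alone). Of the genes grouped with the phase of Arntl, the activators Arntl and Npas2 and the repressor Nfil3 had negative fold changes, and of those grouped with the phase of Dbp, Dbp itself, Per2 (0.89 and 0.60), Nr1d2 (0.64 and 0.45) and Ciart (1.25 and 1.01) had positive ones, with both kinds of cells. Cry1 (0.33 and 0.11) was the exception among the 15. Between syngeneic and allogeneic cells edgeR called 0 of 15 clock genes in either adjustment, with 1 of the 15, Per2, at an unadjusted p below 0.05. In SCI against non-injured cord the called genes were Arntl (0.44), Npas2 (1.15), Nfil3 (0.77) and Cry1 (0.38), which were higher, Dbp (-1.02), Nr1d1 (-0.66), Nr1d2 (-0.45) and Ciart (-0.88), which were lower, and Bhlhe41 (0.49), which was higher, unlike the other called genes grouped with Dbp.

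**Figure D4:**
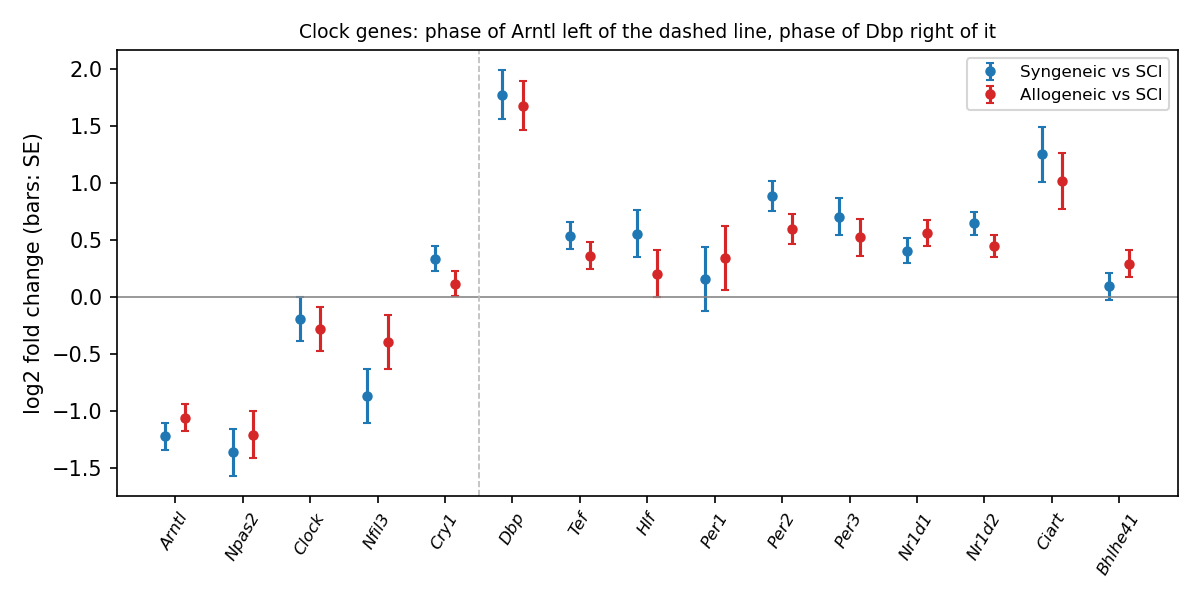
Log2 fold change of 15 clock genes in syngeneic (blue) and allogeneic (red) cells against SCI; bars are the SE of the edgeR fit, genes grouped with the phase of Arntl are left of the dashed line and those grouped with the phase of Dbp right of it. Arntl stood at -1.22 and -1.06, and Dbp at 1.77 and 1.68.

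Both transplanted groups were also compared with non-injured cord, to ask how far each stood from it. With syngeneic cells Atp6v0d2 had a ratio of 513 (91.7 to 20304), Mcoln3 was at least 49.7-fold higher and Slamf7 at least 34.8-fold higher than in non-injured cord. The mitochondrial transfer RNA mt-Tl1 (-1.37, SE 0.30) and Idi1 of cholesterol synthesis (-1.20, SE 0.29) were among the largest falls. With allogeneic cells Cd8a was at least 322-fold higher (724 counts against 0), Slamf7 at least 178-fold higher, and Atp6v0d2 had a ratio of 1744 (313 to 68943). Aqp6 (-2.71, SE 0.45), the inositol transporter Slc5a11 (-2.22, SE 0.51) and Hmgcs1 (-2.18, SE 0.38) were the largest falls. T and NK cell genes were called higher in 4 of 16 cases with syngeneic cells (6 over the list alone; median 2.08, or 1.38 with 4 members at their bound) and in all 16 with allogeneic cells (6.16, or 5.80 with those members at their bound). Cholesterol synthesis genes fell in 5 of 16 cases with syngeneic cells (16 over the list alone; median -0.95) and in all 16 with allogeneic cells (-1.50), and neuronal genes in 0 of 13 (edgeR, -0.26) and 9 of 13 (-0.50).

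edgeR called 813 genes higher and 70 lower with syngeneic cells than in non-injured cord (3188 at an unadjusted p below 0.05), and 2762 higher and 1350 lower with allogeneic cells (6174). For allogeneic cells, library totals as the only scaling gave 3170 and 924, which is 77.4% higher calls against 67.2%. limma camera called 21 lists with syngeneic cells (14 higher) and 22 with allogeneic cells (17 higher), of which 0 held with an estimated correlation (adjusted p from 0.156 and from 0.1504 with an estimated correlation; 10 and 9 lists at an unadjusted p below 0.05), while fry called 16 and 22. In the oligodendrocyte precursor list of both comparisons and the dendritic list with syngeneic cells, the median, mean and test differed in sign. Genes called higher in SCI were shared in 807 cases with the syngeneic and in 2349 with the allogeneic group, against 135 and 457 for independent lists, and genes called lower in 46 and 1014, against 6.48 and 125. The syngeneic and allogeneic groups shared 810 higher and 59 lower genes (136 and 5.72 for independent lists). Lists that share the non-injured libraries are not independent. In 20 simulations of unchanged groups, lists of the same sizes by smallest p, added after the data were seen, shared at most 489 higher and 51 lower genes for SCI with the syngeneic group, 1190 and 459 for SCI with the allogeneic group, and 486 and 45 for both transplanted groups, so part of the overlap may come from those libraries. For syngeneic cells DESeq2 called 1390 genes, limma-voom 2083 and a fit of both groups alone 172, and edgeR 1752 without syngeneic replicate 2, 436 without syngeneic replicate 3, 358 without non-injured replicate 1 and 459 without non-injured replicate 2. For allogeneic cells limma-voom called 7328, a fit of both groups alone 2738, and edgeR 2613 without allogeneic replicate 2 and 2717 without non-injured replicate 1.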

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

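Of the tests in this part, the bounds taken from the injury axis and the fits with the injury index as a covariate were chosen only after the result was seen. The response to the transplant differed between the 2 kinds of cells in a direct edgeR test, with 101 genes called between syngeneic and allogeneic cells. limma camera called 22 gene lists, of which only 1, the T and NK list, held with an estimated correlation. That list had a median log2 fold change of -4.38, with Cd8b1 at -6.62, Cd8a at -5.14, Cxcr6 at -5.12, Ms4a4b at -4.70, Cd3g at -4.58, Cd3e at -4.41 and Ctsw at -3.63. Ly6c2 (-3.70), Ccl5 (-3.40), H2-Q7 (-2.27), Cd74 (-2.19) and H2-D1 (-1.29) were called in the same direction. The 101 called genes fell to 24 and 25 without syngeneic replicate 1 or 2 and to 46 without allogeneic replicate 2, and rose to 1178 without syngeneic replicate 3.

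Blood or lymphoid tissue carried over with the cord would raise red blood cell, neutrophil and B cell genes as well. Their lists had medians of 1.01, 0.73 and 0.76 (allogeneic above syngeneic). The highest upper quartile among them, 1.96, lay below the lower quartile of the T and NK list, 3.66. The lists differ in level, however. Mean CPM in the syngeneic and allogeneic libraries was 0.20 to 0.40 and 3.86 to 7.83 for T and NK genes. It was 12.3 to 32.1 and 29.4 to 67.4 for red blood cell genes. Neutrophil genes stood at 4.29 to 6.24 and 7.49 to 9.80, and B cell genes at 6.49 to 8.19 and 7.31 to 13.3. The same added amount gives a smaller fold change at a higher level, so the fold changes cannot decide on carry-over. Mean CPM in SCI, looked at afterwards, was 0.47 to 0.49 for T and NK genes. It was 8.44 to 11.7 for neutrophil and 41.2 to 51.1 for red blood cell genes. Neutrophil genes were thus not higher with allogeneic cells than in SCI, and red blood cell genes overlapped. That argues against blood as the source of the T and NK rise above SCI. B cell genes (4.39 to 12.7 in SCI) overlapped with a wide spread, which leaves lymphoid tissue open. No single library carried the pattern, since the lowest median of the list over the 6 fits without 1 library was 4.02 and limma camera called the list in each. More lesion in the allogeneic pieces was tested with the injury index as a covariate, and the outcome was split. The median of the 13 called members went from -4.57 to -3.77, 82.5% of its size. The median SE of the single genes, which is not an SE of the list median, went from 0.490 to 0.814. With these wider errors 0 of 13 stayed called in edgeR (all 13 at an unadjusted p below 0.05). Against SCI alone the median of the called members went from 3.68 to 3.43 with 5 of 10 called. The injury axis was extended in a straight line from the rise of the list between non-injured cord and SCI. Over the widest index gap it gave 2.12 between the transplanted groups and 0.611 between allogeneic cells and SCI. The observed lower quartiles, 3.66 and 2.95, lay above these bounds. The slope carries no error and rests on genes with very low levels in non-injured cord, so the bounds are no firm ceiling. A part from more lesion therefore stays open. The match between donor and host, which the design names, may account for the rest as a hypothesis. Carry-over of lymphoid tissue stays open, and so does a part from blood between the transplanted groups. By the numbers in their titles, syngeneic and allogeneic samples form separate ranges. Other differences between the 2 sets of samples that the labels do not record therefore cannot be separated from the match and stay untested.

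For 101 genes between syngeneic and allogeneic cells, 2 of the 10 splits of the 6 libraries into 3 and 3 gave as many, the real one included. The highest other split called 521 genes and set syngeneic replicates 1 and 2 with allogeneic replicate 1 against syngeneic replicate 3 with allogeneic replicates 2 and 3. A count several times the real one points to a structure of the samples that the groups do not describe, and 10 splits are too few for a share under 0.05.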

How the results depend on the processing

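No paired analysis was possible because the replicate numbers follow only the order of the samples and the labels pair none of them. Among the genes picked by the naming rule in the main comparisons, 52 of 58 calls in SCI against non-injured cord, 8 of 12 between the transplanted groups, 0 of 6 for syngeneic cells against SCI and 0 of 11 for allogeneic cells against SCI were kept in all alternatives, and none of these calls changed direction; against non-injured cord 0 of 6 were kept with syngeneic and 6 of 6 with allogeneic cells. RLE factors, library totals and the filter of 1 CPM moved no number of calls, higher and lower together, by over 1.5 times. Higher calls alone went from 3 to 1 between the transplanted groups with library totals. For syngeneic cells against SCI they went from 1 to 2 with RLE factors. In the order SCI against non-injured cord, syngeneic against SCI, allogeneic against SCI, syngeneic against allogeneic, syngeneic and allogeneic against non-injured cord, an adjusted p below 0.01 left 1974, 1, 14, 39, 363 and 2126 genes, and limma-voom called 8229, 38, 87, 371, 2083 and 7328. A 2-fold minimum left 1791 genes in the first and 1903 in the last. DESeq2 called 121, 69, 347 and 1390 genes for both kinds of cells against SCI, between them and for syngeneic cells against non-injured cord, a fit of the compared groups alone 3, 17, 21, 172 and 2738 in all but the first, and no filter gave 18 and 50 for syngeneic and allogeneic cells against SCI. Leaving out 1 library gave 2336 to 3974, 0 to 866, 0 to 29, 24 to 1178, 358 to 1752 and 2613 to 4669 genes, where the wider errors of fewer samples apply to the falls and the cause of the rises was not tested. The injury index as a covariate, added after seeing the data, gave 0 genes for syngeneic cells against SCI (361 at an unadjusted p below 0.05 in edgeR), 13 for allogeneic cells against SCI and 0 between the transplanted groups (236), and leaving out non-injured replicate 3, also as an added alternative, 9, 34 and 121. Gene lists called with an estimated correlation numbered 0, 0, 2, 1, 0 and 0 (6, 7, 4, 4, 10 and 9 at an unadjusted p below 0.05), and fry called 10 for syngeneic and 2 for allogeneic cells against SCI and 10 between them. Reversed signs were seen only in uncalled genes and in the covariance of the fold changes against SCI, which was -0.00918 to 0.0337 with 1 library left out. For syngeneic cells against SCI, Mbp was -0.15 in limma-voom and -0.34 to 0.23 with 1 library left out. For allogeneic cells against SCI, Gfap was 0.00997 with RLE factors, 0.0024 with library totals, 0.0027 with the compared groups alone, 0.00996 in DESeq2, 0.17 in limma-voom and -0.20 to 0.093 with 1 library left out, Snap25 was -0.082 in limma-voom and -0.0615 to 0.11 with 1 left out, and Mbp -0.087 to 0.19 with 1 left out. Between the transplanted groups, Mbp was 0.016 without a filter and -0.38 to 0.19 with 1 library left out, Bdnf 0.069 in limma-voom and -0.16 to 0.047, and Arg1 -1.37 to 0.0136. For the differences between tools and for the reversed signs the cause was not tested. Allogeneic replicate 2 has the lowest depth (8705942 counts), so that genes near the floor are least certain there.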

Other observations

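Of the tests in this part, the clock gene list, the test of collection time, the clock genes' fits with the injury index, their comparison with the non-injured level and the measures of list position after the planned one were chosen only after the result was seen. Libraries of 1 group differed in which gene groups stood near the SCI level. Allogeneic replicate 1 had fibroblast genes at 1.17 and meningeal genes at 0.68 on the log2 scale above the non-injured mean, against 2.54 and 2.44, and 2.51 and 2.51, in the other allogeneic libraries, whereas its T and NK genes (4.34) lay beside theirs (5.27 and 4.28) and its interferon response genes (3.01) above theirs (2.64 and 1.82). Syngeneic replicate 1 had fibroblast genes at 0.26, near non-injured cord, but myelin genes at -0.94, below the SCI libraries (-0.89 to -0.55), and red blood cell genes at -1.30, below all other libraries. Syngeneic replicate 3 had phagocytic myeloid genes at 3.75, within the range of SCI (3.51 to 3.88), and neutrophil genes at 0.25, below SCI (1.39 to 2.03). Schwann cell genes differed most within non-injured cord (-1.79, 0.68 and 1.11), and skeletal muscle genes were highest in non-injured replicate 3 (0.89). Fabp4, the only adipocyte gene tested, ranged from 0.187 to 9.96 CPM over the 12 libraries.

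Clock genes differed between SCI and both transplanted groups. Whether position on the injury axis gives the whole of it was not settled for syngeneic cells. Full return along the axis reaches the non-injured level at 0, whereas 12 of 15 genes, signed by phase, lay beyond it (3 called in edgeR). The lower quartile of the log2 fold change against non-injured cord was 0.149 and the median 0.37. The median SE of the single genes was 0.161, which is not an SE of the median. These values lie beyond the axis but do not decide against it. The list was chosen after its called genes were seen in the same libraries, and genes are not independent replicates. With the injury index as a covariate, 0 of 2 genes called against SCI stayed called. The median went from 0.64 to 0.48 (74.7% kept), while the median SE of the single genes widened from 0.162 to 0.216. For allogeneic cells 127% of the median was kept (0.45 to 0.56, with 2 of 3 called genes still called). That argues against the axis there, within the same limit of how the list was chosen. The median SE of the single genes was 0.163 without and 0.167 with the index. A lower quartile of -0.0025 against non-injured cord decides nothing. A different hour or day of tissue collection stays open, and that 14 of 15 genes moved in the direction of their phase with both kinds of cells does not decide it, because the list was chosen after its called genes were seen and both comparisons share the SCI libraries. By the numbers in their titles, both transplanted groups come from a separate range from SCI and non-injured cord, and they do not overlap with each other. A sample set processed apart and the transplant itself therefore cannot be separated by these data.

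Syngeneic libraries spread between the non-injured and the SCI level. If the pieces held different shares of non-lesioned cord, every gene list would sit at the same position between non-injured cord and SCI in a library, and the planned bound of at least 1 pair of lists apart was met, with 153 and 143 of 300 pairs apart in syngeneic replicates 1 and 2 (95th percentile of shuffled lists 37 and 36). That bound was wrong, because the SCI libraries themselves had 91 to 127 pairs apart. Further measures, taken without the immediate early and heat shock list, differed. The widest gap between the other lists was 0.923 in replicate 1 and 0.277 in replicate 2, beside at most 0.623 in SCI. The ratio of the same quartiles was 8.73 and 4.04 beside at most 1.96, which small denominators inflate. In replicate 2 the omitted list had an upper quartile of 0.0216, below the 0.0913 of oxidative phosphorylation, the lowest list used. Gap and ratio there would be larger with it. Different shares of non-lesioned cord and a milder injury response with syngeneic cells therefore cannot be told apart, and the latter may hold in some lists of replicate 1.

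Other splits of the 6 libraries of each comparison into 3 and 3 were counted in the same fit of 12 libraries. For SCI against non-injured cord (4266 genes), syngeneic cells against SCI (6), allogeneic cells against SCI (31) and syngeneic cells against non-injured cord (883), the highest other split called 0 genes in edgeR, and 1 of the 10 splits, the real one, gave as many. For allogeneic cells against non-injured cord (4112), the highest other split called 1645 genes, with allogeneic replicate 1 and non-injured replicates 1 and 2 set against the other 3 libraries, and again 1 of 10 gave as many. With 10 splits no share under 0.05 is possible.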
